A study of Mus musculus with 6 samples.

How the data were processed

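RNA was measured in lung tissue of 6 wild type mice, 3 kept on a control diet and 3 on a high fat diet, with 1 array per mouse. Per the labels, total RNA was extracted with a Qiagen RNeasy kit and labelled with biotin by the Affymetrix procedure. The probe sets are those of the Affymetrix Mouse Genome 430 2.0 array, on which most probe sets hold pairs of a matching and a mismatched probe near the 3' end of a transcript. The length of the diet and the age, sex and strain of the mice are not given in the sources used here, nor are dates of labelling or scanning, so no batch could be tested. The sample titles carry numbers that lie in separate ranges for the control and the high fat mice. What these numbers stand for is not given, and a batch that follows them could not be told apart from diet.

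Per the submitters' processing notes, the authors made the deposited values with MAS5, the Affymetrix algorithm that turns the probes of a probe set into 1 signal per array. The version and settings of MAS5 are not given in the sources used here. The deposited values are intensity values on a linear scale, all above 0. On every array the mean signal without the highest and lowest 2 percent of probe sets was 500, so the arrays had been scaled to a common trimmed mean. Such scaling removes any difference in total signal, and a signal is relative to the other probe sets of its array. MAS5 subtracts mismatch signal, which makes dim probe sets noisy, and no detection calls were used here. The precision of every value is limited by the number of arrays, 3 per group.

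Gene symbols came from the platform annotation. Of 45101 probe sets, 34958 carried 1 symbol, 932 carried several and 9211 carried none. Of all probe sets, 64 were Affymetrix controls, which were not tested. Symbols were looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which found 34754 probe sets and changed 0 symbols. No coordinates are given, because the files name no genome build. Probe sets with several symbols or none were tested but name no gene.

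Values below 1 were set to 1 and log2 was taken, with no further normalization. Probe sets were kept if their mean log2 signal over the 6 arrays reached the 40th percentile, a log2 value of 6.14 or a signal of 70.3, which left 27022. The test was limma's (version 3.58.1, in R 4.3.3), lmFit followed by eBayes with an intensity trend, two-sided, with 1 term for diet and 4 residual degrees of freedom. Benjamini-Hochberg adjustment was made over all tested probe sets, and for genes over 12689 representatives. The representative of a gene is its brightest probe set that names only that gene. A call is an adjusted p under 0.05. Log2 differences are high fat minus control and folds are 2 to that power. Means and SDs are of linear signals over 3 mice. Where a gene has other tested probe sets, their signs were compared with that of the representative.

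Before the data were examined, 46 lists of genes were fixed, covering metabolism, immune responses, stress, clock and matrix genes, and markers of lung cell types and of neighbouring tissues. Of these, 43 had at least 5 tested members. The 3 others, markers of mast cells, eosinophils and basophils, of the oesophagus and other neighbouring tissue, and of liver, had 4, 4 and 3 tested members. Lists were tested with camera, which asks whether members are shifted relative to other genes, at a preset inter-gene correlation of 0.01, adjusted over the 43 lists. Camera with an estimated correlation and fry were alternatives. Members called are also counted adjusted over the list alone. A score per array is the mean log2 signal of the tested members minus the mean of the control arrays.

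Genes named in the text follow a rule fixed before the data were examined. It takes the 15 largest rises and 15 largest falls among called genes without overlap between groups, up to 4 members by smallest p from each list called or holding a member called over the list alone, and a set of reference genes. Symbols of predicted genes and clones were left out. Cpt1a, Ndufa4, Lrrn4, Cidec, Cxcl1, Atp6v0d2, Ucp1 and Nnt are named in addition and were chosen after their values were seen. The rule also did not select Tef, Hlf and Nr1d1, named as further clock outputs, or Lpl and Slc2a4, named as members of several lists.

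RNA quality was judged by the ratios of the 3' to the 5' control probe sets of Gapdh and b-Actin, with two-sided exact permutation tests over 20 relabelings, for which the smallest possible p is 0.1. Alternatives were quantile normalization, centring on the array median, adding 32 before log2, no filter and a filter at the 60th percentile, eBayes without trend and with robust estimation, array weights, the replicate number as a block, other rules for the representative, and leaving out each mouse. A fit without control replicate 1 and high fat replicate 1 was added after the data were seen, because these had the highest skeletal muscle scores. The other samples were not free of muscle transcripts.

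The procedure was tested on simulated data for the high fat against control comparison, with 12729 simulated genes passing the filter. It recovered 0 of 69 genes changed by 0.5 on the log2 scale, 22 of 54 changed by 1 (40.7 percent) and 49 of 53 changed by 2 (92.5 percent). Of 73 simulated calls, 1 was false. Most changes of 2-fold or less were therefore missed in the simulation. The simulation drew noise independently for each probe set and changed few genes. Its shares do not carry over to the data, where 857 genes were called, 243 of them at least 2-fold. Figures were drawn with matplotlib 3.10.9.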

Results

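Transcript levels were measured in the lungs of 6 wild type mice on Affymetrix arrays, with 1 array per mouse, 3 mice on a control diet and 3 on a high fat diet. The comparison asks which lung transcripts differ between the diets. Signals are MAS5 intensities scaled by the authors to a common trimmed mean of 500. The median signal of all probe sets was 145.1, 150.3 and 143.3 on the control arrays and 121.2, 113.4 and 128.7 on the high fat arrays. Correlations of log2 signals across probe sets, which are not independent replicates, were 0.945 to 0.962 among control arrays, 0.951 to 0.961 among high fat arrays and 0.902 to 0.938 between the groups. The first principal component held 45.4 percent of the variance and separated the diets.

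Several properties of the samples differed between mice. The ratio of the 3' to the 5' control probe set of Gapdh was 0.768 ± 0.026 (SD, n = 3) in control and 0.915 ± 0.054 (SD, n = 3) in high fat mice, and that of b-Actin was 1.306 ± 0.122 and 1.522 ± 0.022. Neither ratio overlapped between groups, each with an exact permutation p = 0.1, the smallest that 3 against 3 allows. The ratio of the 3' to the middle probe set did not separate the groups (Gapdh 0.986 and 0.99, exact permutation p = 1; b-Actin 1.235 and 1.281, exact permutation p = 0.5). The skeletal muscle score was highest in control replicate 1 (2.8 on the log2 scale) and high fat replicate 1 (1.3) and below 0 in the other mice. The cardiac muscle score was highest in high fat replicate 1 (2.33), followed by high fat replicate 3 (0.83) and control replicates 1 and 3 (0.39 and 0.38). A score below 0 does not mean that muscle was absent, since scores are relative to the control mean. Adipocyte marker scores were -0.63, -0.16 and 0.79 in control mice and 2.61, 1.6 and 1.92 in high fat mice. Xist, which is expressed from the inactive X chromosome of females, had a low signal in both groups (145 ± 27.7 and 124 ± 115, SD, n = 3 each).

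Lungs of high fat mice had much higher signals for several adipose tissue transcripts. Called genes with lower signals included some immunoglobulin, lymphocyte and neutrophil genes, the clock output gene Dbp and Cyp1a1. Among called genes, the largest rise was that of Alox15, a lipoxygenase that oxidises polyunsaturated fatty acids. Its signal went from 112 ± 31 to 1220 ± 287 (SD, n = 3 each), which is 10.9-fold (limma adjusted p = 0.00125). A called probe set that does not name 1 gene rose 49.3-fold. Prg4, a lubricating glycoprotein, rose 10.1-fold, the adipocyte hormone Adipoq 9.71-fold, Ifi27l2a, an interferon-inducible gene, 8.13-fold, and the fatty acid carrier Fabp4 7.66-fold (limma adjusted p = 0.00218, 0.00795, 0.000214 and 0.00218). Also among the 15 largest rises were Mrap, Pck1, Saa3, Cxcl2, Tmem45b, Cox8b, Alb, Orm1, Retn and Aoc3, between 5.31-fold and 9.34-fold. Among genes named by the rule, the largest fall was that of an immunoglobulin kappa variable gene, to 0.0989 times the control level. Grp, which encodes gastrin-releasing peptide, followed at 0.129 times (limma adjusted p = 0.04 and 0.0066). The kappa gene had control signals of 4050, 2391 and 313, and with 1 mouse left out its log2 difference ran from -4.44 to -2.6 and was called in 1 of 6 fits. Cyp1a1, a xenobiotic-metabolising cytochrome P450, fell to 0.21 times, from 2050 ± 1120 to 452 ± 310 (SD, n = 3 each, limma adjusted p = 0.0307). Angptl1, Cd8b1, Cd244a, S100a9, Siglecf, Mmp8, Esm1, Dbp, Igkv4-68, Ear3, Il1b and Sprr2k completed the 15 largest falls, between 0.228 and 0.323 times the control level. Mean signals lay below 70.3 in control mice for Mrap, Cxcl2 and Alb and in high fat mice for Grp, Angptl1, Siglecf, Mmp8, Igkv4-68 and Sprr2k, so the size of these folds is uncertain.

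**Figure D1:**
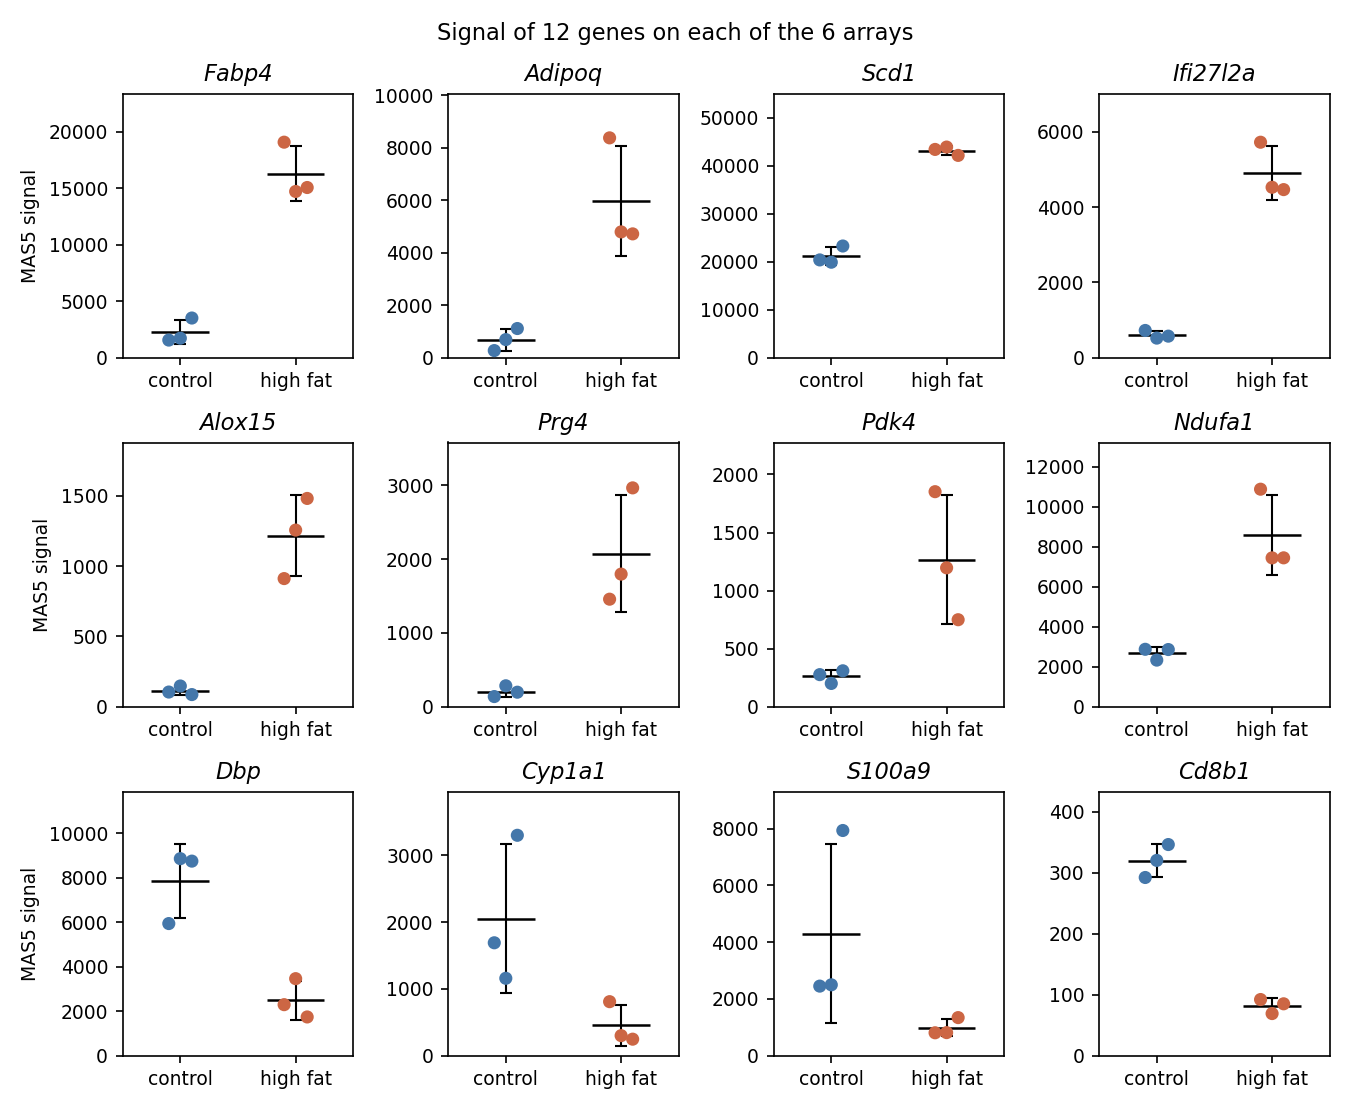
MAS5 signal (linear, arbitrary units, vertical axis from 0) of 12 genes in lungs of control (blue) and high fat (orange) mice, with 1 point per array, a line at the mean and bars of 1 SD (n = 3). The groups did not overlap in any of the genes, from Fabp4 (2260 ± 1080 against 16300 ± 2420) to Cd8b1 (320 ± 26.7 against 82 ± 11.6). Most of these genes were picked among those without overlap, so this follows from the choice.

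In all, 857 of 12689 genes were called, 578 higher and 279 lower in high fat mice, and 243 of these differed at least 2-fold (152 higher, 91 lower). The share of calls that were higher was 67.4 percent, against 83.2 percent with arrays centred on their median. Over 27022 probe sets, 3486 were called, 1251 higher and 2235 lower, so 35.9 percent were higher, against 44.8 percent with quantile normalization and 51.9 percent with median centring. The groups did not overlap for 4029 genes (31.8 percent, where chance gives 10 percent). The count of genes depended on each mouse and on the variance model. It was 354, 206 and 160 without control replicate 1, 2 or 3 and 521, 398 and 566 without high fat replicate 1, 2 or 3, with 0 changes of sign among the 857 genes. It was 136 without an intensity trend, 515 with the mean of all probe sets per gene, and 307 without replicate 1 of both groups, a fit chosen after seeing the data. Of the 15 largest rises, 10 stayed called in every fit with 1 mouse left out, and Saa3, Cxcl2, Cox8b, Alb and Retn did not (highest adjusted p 0.119, Retn without control replicate 2). Of the 15 largest falls, Grp, Angptl1, Cd8b1, Cd244a, Esm1 and Dbp stayed called in every such fit, and Sprr2k in none (up to 0.154, without control replicate 3). Of 3 dimmer tested probe sets of Fabp4, 1 was called (2.6 on the log2 scale) and 2 were not (0.33 and 0.71), nor were those of Pck1 (1.6) and Cd244a (-0.49).

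Of 43 fixed lists, camera called 21, 14 toward higher and 7 toward lower signals in high fat mice. With an estimated correlation it called 0 (1 at an unadjusted p under 0.05), and the adjusted p of every list called was then 0.59 to 0.67. Fry called 1, fatty acid synthesis (adjusted p = 0.016). Other splits of the 6 mice, which mix the diets, gave up to 18 called lists and at most 2 called genes. A mixed split adds the diet difference to the spread within its groups, so its few called genes do not measure false calls. Since mixed splits also gave many called lists, the account of each list rests on its members called one by one. Over all genes, 857 of 12689 were called and 3238 had an unadjusted limma p under 0.05. A list with few called members, also when adjusted over the list alone, can lie near these shares, and such counts are then no evidence about the list.

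**Figure D2:**
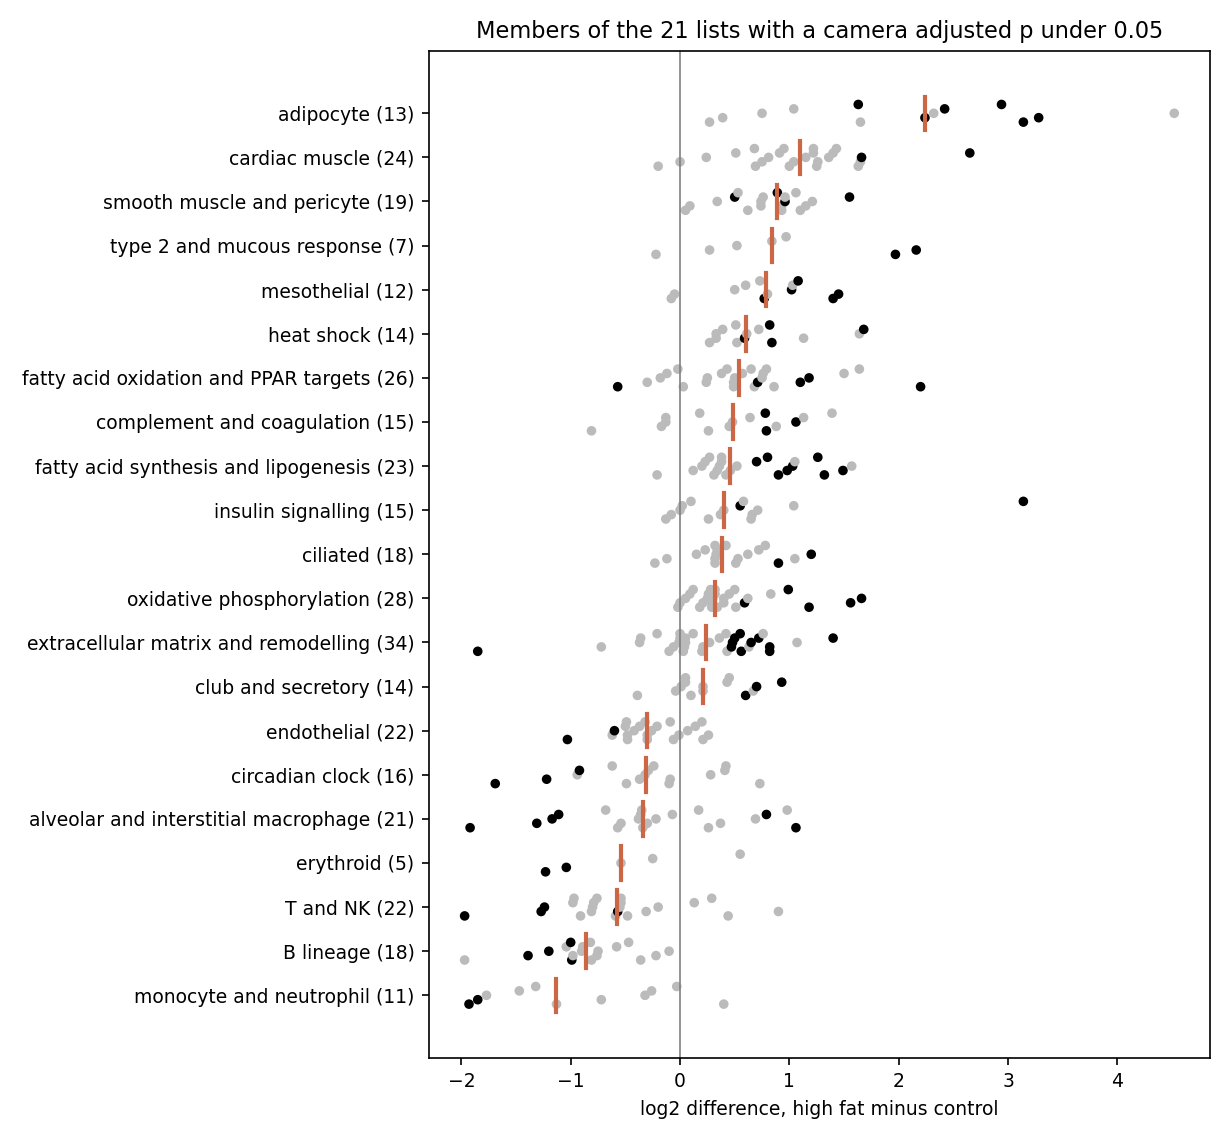
Log2 difference (high fat minus control, horizontal axis) of each tested member of the 21 lists called by camera, with the number tested in brackets; black points are genes with an adjusted p under 0.05 over all genes, grey points are not called, and the orange line is the list's median. Medians ran from -1.13 (monocyte and neutrophil markers) to 2.24 (adipocyte markers).

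Some adipocyte markers and lipid synthesis enzymes were higher in high fat mice, and none was called lower. Of 13 adipocyte markers, 6 rose, 0 fell and 7 were not called, and 11 rose adjusted over the list alone (median 2.24 on the log2 scale, camera adjusted p = 2.48e-07, adjusted p = 0.59 with an estimated correlation). Besides Fabp4 and Adipoq, these were Plin4, a lipid droplet protein (366 ± 92.6 to 1730 ± 483, SD, n = 3 each), Pck1, the gluconeogenic and glyceroneogenic enzyme (8.83-fold), Retn (5.34-fold) and Cidec (1.63 on the log2 scale). The log2 difference of Retn ran from 1.65 to 3.04 with 1 mouse left out. Ucp1, the uncoupling protein of brown fat, was not called (limma adjusted p = 0.0857). Its control signals were 3, 25 and 258, and its log2 difference ranged from 2.38 to 6.17 over the alternatives. Of 23 genes of fatty acid synthesis and lipogenesis, 8 rose and 0 fell, and 15 rose adjusted over the list alone (median 0.46, camera adjusted p = 1.79e-07, adjusted p = 0.59 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, rose from 21200 ± 1830 to 43200 ± 896 (SD, n = 3 each; 2.04-fold, limma adjusted p = 0.00613), and Pnpla3 rose 2.81-fold, the acetyl-CoA synthetase Acss2 1.74-fold and the acetyl-CoA carboxylase Acacb 1.98-fold. In contrast, of 20 genes of cholesterol synthesis, only Insig1 was called (1.62-fold, median of the list -0.01, camera adjusted p = 0.468). The medians ran from 1.56 to 2.44 for adipocyte markers and 0.4 to 0.57 for lipogenic genes with 1 mouse left out. Called adipocyte markers numbered 4 to 8 and lipogenic genes 3 to 9 with 1 mouse left out, both lowest without control replicate 2. Fabp4, Adipoq, Plin4, Pck1, Scd1 and Pnpla3 stayed called in all of these fits, while Acss2, Acacb and Cidec did not (0.0526, 0.0559 and 0.0553 without control replicate 2; Acss2 0.538 with the mean of all its probe sets), nor did Insig1 (0.109 without control replicate 3).

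A minority of the genes of mitochondrial fat oxidation and of the respiratory chain were called higher. The high fat samples had more adipocyte transcripts and, in replicates 1 and 3, higher cardiac muscle scores than any control mouse. Of 26 fatty acid oxidation genes and PPAR targets, 4 rose and 1 fell, and 13 rose and 1 fell adjusted over the list alone (median 0.54, camera adjusted p = 0.000447, adjusted p = 0.62 with an estimated correlation). The genes that rose were Pdk4, the kinase that restrains pyruvate oxidation (262 ± 55.8 to 1270 ± 555, SD, n = 3 each; limma adjusted p = 0.00811), Cpt2 (2.27-fold), Acot2 (2.14-fold) and Acads (1.63-fold), and Cpt1a fell (log2 -0.57). Of 28 oxidative phosphorylation genes, 5 rose and 0 fell, and 10 rose adjusted over the list alone (median 0.32, camera adjusted p = 3.25e-05, adjusted p = 0.67 with an estimated correlation). These were the complex I subunits Ndufa1 (3.16-fold) and Ndufa5 (2.94-fold), Ndufa4 (log2 0.59), and the cytochrome c oxidase subunits Cox6c (2.26-fold) and Cox5b (1.98-fold). With the mean of all probe sets of a gene, Cox5b turned to -0.07 through 2 probe sets that failed the filter (-2.27 and -1.68), while its 4 tested ones rose (0.7 to 0.99, all called over probe sets). Cpt1a was at -0.09 with that mean, and Acot2 was not called (0.56, limma adjusted p = 0.077). Oxidative phosphorylation scores were 0.83, 0.2 and 0.36 in the 3 high fat mice. Of 24 cardiac muscle markers, Cox8b (6.26-fold) and the atrial light chain Myl7 (3.16-fold) rose (median 1.1, camera adjusted p = 0.000771, adjusted p = 0.67 with an estimated correlation). Across the high fat mice Cox8b (2068, 382 and 850) had the same order as Myl7 (27792, 12042 and 14673) and as Ucp1 (1199, 236 and 748). Its rise can therefore not be assigned to heart muscle alone. Of 15 skeletal muscle markers limma called 0, and 0 at an unadjusted p under 0.05 (median -0.87, camera adjusted p = 0.128, but 0.0263 with median centring, 0.028 with no filter and 0.0102 with the replicate block), and of 15 glycolytic genes only Pfkl (1.67-fold). Without replicate 1 of both groups, the medians were 0.36 for fat oxidation, 0.13 for oxidative phosphorylation and 0.66 for cardiac muscle. With 1 mouse left out they ran from 0.32 to 0.67, 0.12 to 0.49 and 0.5 to 1.64. The median of skeletal muscle markers then ran from -2.15 to 0.47, so its sign depended on 1 mouse. Pdk4, Ndufa1, Cox6c and, by its representative, Acot2 stayed called with any 1 mouse left out, while Cpt2 (0.0556 without control replicate 3), Ndufa5 (0.0524 without control replicate 2), Cox5b, Acads, Cpt1a, Ndufa4, Cox8b, Myl7 and Pfkl did not (up to 0.16, Cpt1a without control replicate 3).

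**Figure D3:**
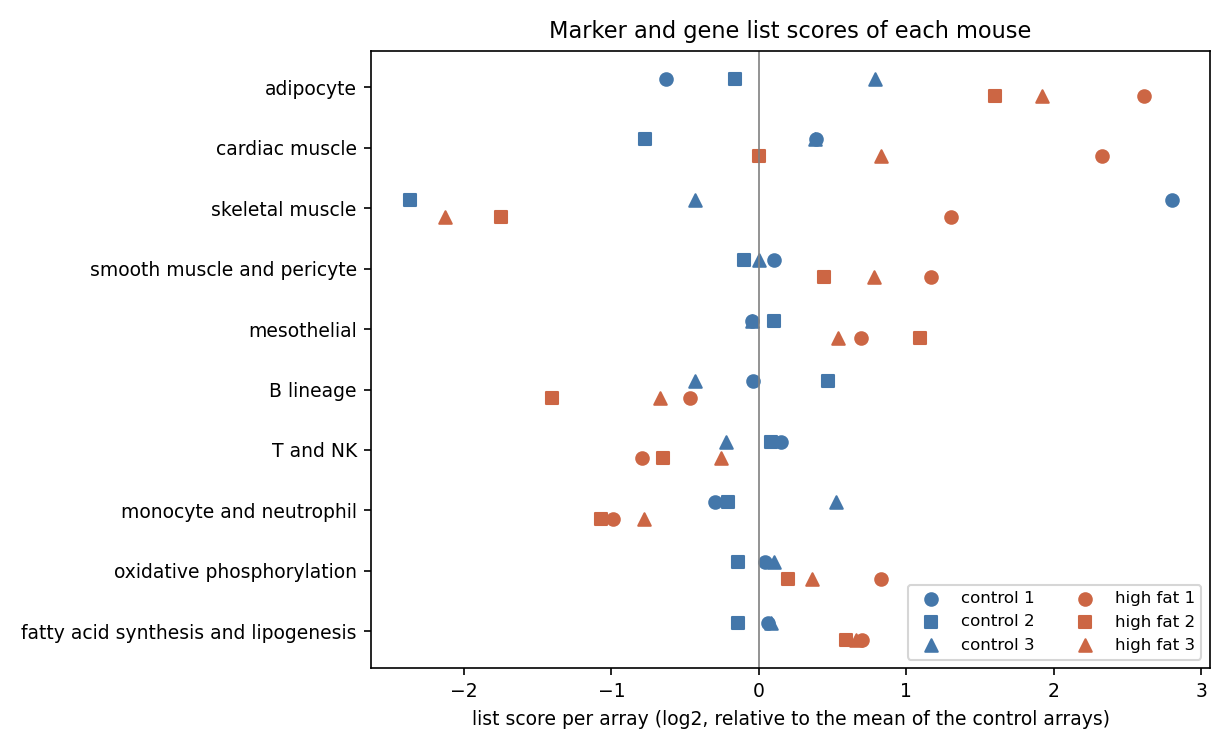
Score of 10 lists in each mouse (mean log2 signal of the tested members relative to the control mean, horizontal axis), with control mice in blue, high fat mice in orange and a marker shape per replicate number. Adipocyte scores of high fat mice lay between 1.6 and 2.61 and those of control mice between -0.63 and 0.79, whereas skeletal muscle scores were highest in replicate 1 of both groups (2.8 and 1.3).

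Some lymphocyte and neutrophil markers were lower in high fat mice, and none was called higher. Of 18 B lineage markers, 0 rose and 4 fell, 6 adjusted over the list alone (median -0.86, camera adjusted p = 2.42e-06, adjusted p = 0.59 with an estimated correlation). They were Ms4a1, which encodes CD20 (1710 ± 432 to 674 ± 242, SD, n = 3 each), Cd22, Fcmr and Fcer2a, at 0.382 to 0.504 times the control level. Of 22 T and NK cell markers, 0 rose and 4 fell, 8 adjusted over the list alone (median -0.58, camera adjusted p = 4.24e-06, adjusted p = 0.59 with an estimated correlation). Cd8b1, the CD8 beta chain, fell from 320 ± 26.7 to 82 ± 11.6 (SD, n = 3 each; limma adjusted p = 0.00425), Ms4a4b to 0.416 times, the NK receptor Ncr1 to 0.423 times and the IL-7 receptor Il7r to 0.676 times. Of 11 monocyte and neutrophil markers, S100a9 and the neutrophil collagenase Mmp8 fell to 0.263 and 0.277 times, 5 fell adjusted over the list alone (median -1.13, camera adjusted p = 0.000771, adjusted p = 0.59 with an estimated correlation). S100a9 varied among control mice, with signals of 2452, 2498 and 7938. With 1 mouse left out the medians ran from -1.06 to -0.41 for B lineage, -0.79 to -0.47 for T and NK and -1.53 to -0.89 for neutrophil markers. Cd8b1 alone stayed called in every such fit; called B lineage markers then numbered 0 to 4, T and NK markers 1 to 6 and neutrophil markers 0 to 3, and the highest adjusted p was 0.152 for Il7r without control replicate 2. Without replicate 1 of both groups, 0 B lineage markers, 1 T and NK marker and 3 neutrophil markers were called.

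Macrophage markers moved in both directions. Of 21, 2 rose and 4 fell, and 5 rose and 7 fell adjusted over the list alone (median -0.34, camera adjusted p = 0.034, adjusted p = 0.67 with an estimated correlation). Those that fell included Siglecf, a lectin of alveolar macrophages and eosinophils (221 ± 21.5 to 61.3 ± 23.5, SD, n = 3 each), the keratin Krt79 (0.403 times), the lysosomal protein Cd68 (0.465 times) and Atp6v0d2 (log2 -1.17). The complement genes C1qa (2.09-fold) and C1qb (1.72-fold) rose, as did C1qc (1.72-fold), and these were the 3 called genes of 15 in the complement and coagulation list (6 adjusted over the list alone, median 0.48, camera adjusted p = 0.0112, adjusted p = 0.62 with an estimated correlation). Of 5 erythroid markers, Alas2 (0.487 times) and Hbb-b2 (0.428 times) fell (median -0.54, camera adjusted p = 0.0375, adjusted p = 0.61 with an estimated correlation), and Hbb-b2 turned to 0.08 with the mean of its 2 probe sets, the other of which failed the filter (log2 1.38). Of 22 endothelial markers, the sialomucin Emcn (0.49 times) and Pecam1 (0.661 times) fell, and 3 fell adjusted over the list alone (median -0.3, camera adjusted p = 0.000512, adjusted p = 0.62 with an estimated correlation). C1qa alone stayed called with any 1 mouse left out. In these fits the medians ran from -0.38 to -0.26 for macrophage, 0.29 to 0.69 for complement, -0.8 to -0.3 for erythroid and -0.39 to -0.16 for endothelial genes. The macrophage list was not called by camera without control replicate 1 or high fat replicate 1 (adjusted p up to 0.177) or without both of these mice (0.324). The erythroid list was not called without high fat replicate 2 or 3 (up to 0.0898) or with no filter on dim probe sets (0.159), and neither list with eBayes without trend (0.0558). The complement list was not called without members that lists share (0.0653).

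A minority of smooth muscle, mesothelial and matrix genes were called higher, and smooth muscle scores were highest in high fat replicate 1, the mouse with the highest cardiac muscle score (1.17, 0.44 and 0.78 in the high fat mice). Of 19 smooth muscle and pericyte markers, 4 rose and 0 fell, and 14 rose adjusted over the list alone (median 0.89, camera adjusted p = 4.24e-06, adjusted p = 0.59 with an estimated correlation). They were calponin Cnn1 (1030 ± 222 to 3290 ± 1880, SD, n = 3 each), Myl9 (1.95-fold), transgelin Tagln (1.85-fold) and Notch3 (1.41-fold). Of 12 mesothelial markers, 5 rose and 0 fell, and 10 rose adjusted over the list alone (median 0.79, camera adjusted p = 4.93e-05, adjusted p = 0.59 with an estimated correlation), among them the uroplakin Upk3b (2.65-fold), the transcription factor Wt1 (2.74-fold), Igfbp5 (2.12-fold), Krt8 (1.71-fold) and Lrrn4 (log2 1.02). Of 34 matrix and remodelling genes, 10 rose and 1, Mmp8, fell, and 13 rose adjusted over the list alone (median 0.24, camera adjusted p = 0.0128, adjusted p = 0.59 with an estimated correlation, and 0.197 by camera with quantile normalization). Elastin, Eln, rose from 496 ± 59.7 to 1330 ± 298 (SD, n = 3 each; limma adjusted p = 0.0066), the collagen chaperone Serpinh1 1.64-fold, Col5a1 1.76-fold and Mmp14 1.56-fold. Eln stayed called with any 1 mouse left out. Igfbp5 did too by its representative, but its other tested probe set had a log2 difference of 0.07 (limma adjusted p = 0.887 over probe sets), and it was not called with the mean of its probe sets (0.13). Called members numbered 0 to 7 for smooth muscle, 1 to 7 for mesothelial and 1 to 6 for matrix genes in these fits, each lowest without control replicate 3, and their medians ran from 0.57 to 1.1, 0.66 to 0.96 and 0.15 to 0.39. Camera did not call the matrix list without high fat replicate 2 (0.0729).

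Few epithelial markers were called. Sftpc, the surfactant protein C gene, was at 48100 ± 19000 and 49900 ± 6480 (SD, n = 3 each, limma adjusted p = 0.818). Scgb1a1, the club cell secretoglobin, was at 55100 ± 19200 and 61300 ± 5510 (SD, n = 3 each, limma adjusted p = 0.632). The highest signals of the arrays ran from 38296 to 75983, so both genes lay near the top of the scale. A difference could be understated there, and these values do not show that the 2 genes were unchanged. Of 16 type II markers only Lgi3 was called (1.52-fold, with 0.01 and 0.02 on the log2 scale in its other tested probe sets, median of the list 0.27, camera adjusted p = 0.0672, but 0.0288 with no filter, 0.0346 with array weights, 0.0484 with the replicate block and 0.0306 without shared members). Of 13 type I markers only Akap5 was called (0.567 times, median -0.11, camera adjusted p = 0.0749). Other probe sets of the type I markers Emp2 (-1.59), Clic5 (-2.1 and -0.71) and Col4a3 (-1.48) were called lower over probe sets. Their representatives fell by less (-0.6, -0.53 and -0.54) and were not called over genes. Among all 10236 other probe sets of named genes, 1034 were called lower and 332 higher, so such falls are not particular to type I markers. The type I list was called lower with quantile normalization (median -0.31, 0.00122), with the replicate block (0.0347) and without replicate 1 of both groups (0.0448). Of 18 ciliated cell markers, the dynein light chain Dynlrb2 (2.3-fold) and Cfap126 (1.87-fold) rose, 5 adjusted over the list alone (median 0.38, camera adjusted p = 0.00124, adjusted p = 0.67 with an estimated correlation). Ciliated scores were 0.87, 0.21 and 0.32 in the high fat mice, and without replicate 1 of both groups the camera adjusted p was 0.0684. Of 14 club and secretory markers, Aldh1a7 (1.91-fold), haptoglobin Hp (1.51-fold) and Gabrp (1.63-fold) rose (median 0.21, camera adjusted p = 0.0427, adjusted p = 0.67 with an estimated correlation). Without replicate 1 of both groups the club list turned to a median of -0.01 (camera adjusted p = 0.586). It was not called without high fat replicate 1 (0.862), without control replicate 1 or high fat replicate 3, or with quantile normalization (0.211), median centring (0.0863), a filter at the 60th percentile (0.0703), array weights (0.075) or eBayes without trend (0.0558). With 1 mouse left out the medians ran from 0.23 to 0.58 for ciliated, 0.02 to 0.66 for club, 0.22 to 0.38 for type II and -0.27 to -0.04 for type I markers. Aldh1a7 alone stayed called with any 1 mouse left out, and Lgi3, Akap5, Hp, Gabrp, Dynlrb2 and Cfap126 did not (up to 0.122, Gabrp without control replicate 2).

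Some heat shock genes were higher and Il1b was lower in high fat mice. Of 14 heat shock genes, 4 rose and 0 fell, and 8 rose adjusted over the list alone (median 0.6, camera adjusted p = 1.6e-05, adjusted p = 0.59 with an estimated correlation). They were Hsph1 (854 ± 238 to 2940 ± 1610, SD, n = 3 each), Dnaja1 (1.79-fold) and the mitochondrial chaperonins Hspe1 (1.77-fold) and Hspd1 (1.51-fold). Of 21 genes of the unfolded protein response, Calr (1.58-fold), Creld2 (1.89-fold) and Manf (1.53-fold) rose (median 0.07, camera adjusted p = 0.18, and 0.0448 without replicate 1 of both groups). Among 18 inflammatory genes, 4 rose and 1 fell (median 0.34, camera adjusted p = 0.179, and 0.00518 without those 2 mice). Saa3, an acute phase protein, rose 7.53-fold, and the neutrophil chemokines Cxcl1, Cxcl2 and Cxcl5 were called higher. The control means of Cxcl2 and Cxcl5, 42.2 and 41.1, are too dim for a reliable fold. Il1b fell from 1090 ± 226 to 357 ± 124 (SD, n = 3 each; limma adjusted p = 0.0151). Of 7 genes of the type 2 and mucous response, Retnla (3.92-fold) and the anion exchanger Slc26a4 (4.46-fold) rose, 3 adjusted over the list alone (median 0.84, camera adjusted p = 0.034, adjusted p = 0.62 with an estimated correlation). Of 27 interferon-stimulated genes only Ifit1 rose (1.69-fold, median 0.04, camera adjusted p = 0.849). None of these genes stayed called in every fit with 1 mouse left out, and called members then numbered 0 to 4 for heat shock, 0 to 6 for inflammatory and 0 to 2 for type 2 genes. The medians of heat shock and type 2 genes ran from 0.53 to 0.77 and 0.53 to 1.23. The type 2 list was not called by camera without control replicate 2 or 3 or high fat replicate 2 or 3 (up to 0.114) or with no filter on dim probe sets (0.384), median centring (0.0589) or eBayes without trend (0.0551).

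Of 16 circadian clock genes, 0 rose and 3 fell, and 1 rose and 4 fell adjusted over the list alone (median -0.31, camera adjusted p = 0.00603, adjusted p = 0.59 with an estimated correlation). Dbp, a clock-driven transcription factor, fell from 7850 ± 1650 to 2500 ± 880 (SD, n = 3 each; limma adjusted p = 0.0102). It fell by less in its other tested probe set (log2 -0.97 against -1.69). Per2 was at 0.529 times the control level. Per3 was at 0.43 times by its representative, but its 4 other tested probe sets had log2 differences of -0.99 (called over probe sets), -0.57, 0.12 and 0.05, and it was not called with the mean of all its probe sets (-0.6, limma adjusted p = 0.334). Among other clock outputs, Tef, Hlf and Nr1d1 were not called (limma adjusted p = 0.252, 0.328 and 0.793). Arntl, which peaks in the opposite phase to Dbp, was at 205 ± 36.1 and 307 ± 159 (SD, n = 3 each; limma adjusted p = 0.593). The time of day of tissue collection is not given in the sources used here. Among 15 insulin signalling genes, Pck1 and Akt2 (1.46-fold) rose, 3 adjusted over the list alone (median 0.4, camera adjusted p = 0.0128, adjusted p = 0.59 with an estimated correlation, and 0.0515 by camera with quantile normalization). Akt2 turned to -0.06 with a representative not marked as cross-hybridising. Of 14 AhR and xenobiotic genes, Cyp2s1 rose (1.8-fold) and Cyp1a1 fell (median 0.02, camera adjusted p = 0.961). With 1 mouse left out the medians ran from -0.49 to -0.12 for the clock list, with 1 to 3 called members, and from 0.33 to 0.48 for the insulin list. Dbp stayed called in every such fit, whereas Per2 (0.0596 without control replicate 3), Per3 (0.0624 without control replicate 2), Akt2, Cyp2s1 and Cyp1a1 did not, and the insulin list was not called without control replicate 1 (0.062) or without members shared by lists, such as Pck1 (0.0601).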

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

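The tests of brightness, RNA quality, heart muscle or brown fat, adipose tissue and normalization in this part were chosen after the results they address had been seen, and the tests of nuclear RNA, short transcripts and the adipocyte covariate before.

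The control probe sets for mouse transcripts were compared between the diets only in the Gapdh and b-Actin ratios. Of these probe sets, 3 reached at least 2.1 times the highest control array in a high fat mouse, and only those past 2 times are listed. The 5' probe set of 18S ribosomal RNA reached 23040 in high fat replicate 2, which is 5.7 times the highest control array (4029). The 3' probe set of pyruvate carboxylase, an enzyme abundant in fat and liver, reached 1135 in a high fat mouse against 459 (2.5 times), and its middle probe set reached 257 against 123 (2.1 times).

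Of 4097 tested probe sets that carry several gene symbols or none, called unnamed here, 808 fell and 123 rose in high fat mice. Their median was -0.457 on the log2 scale, but 0.013 and 0.128 in the brightest 2 deciles. Representatives of named genes had 393 falls and 796 rises, and other probe sets of named genes 1034 falls and 332 rises (median -0.147), so the pattern is not confined to unnamed probe sets. Scaling that depends on brightness is argued against, since named representatives of the same brightness had a median of 0.037 ± 0.008 (SE). A lower share of nuclear-retained RNA stays open, because 13 such RNAs had a median of -0.106 ± 0.116 (SE). RNA quality cannot be told apart from diet: the Gapdh ratio separates the groups, and within groups the slope of unnamed minus named signal on that ratio was 1.01 ± 0.66 (SE, 6 arrays), and diet itself stays open and untested.

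Respiratory chain and ATP synthase subunits rose, 32 of 79 with 0 falls and a median of 0.59, a family chosen after the data were seen. Better recovery of short transcripts stays open. Of 54 genes for other small proteins, 12 rose and 2 fell, and their median stood 0.2997 above that of named genes of the same brightness, just under the 0.3 set in advance and above all 1000 random draws. Some of those that rose encode mitochondrial proteins, so the list does not separate short transcripts from mitochondrial content. More heart muscle or brown fat stays open too: the 10 subunits of 300 residues or more, which are not short, had a median of 0.303 ± 0.067 (SE), and 0.5 of that of all subunits lies within this spread. A response of lung cells to the diet would raise these as well, stays open and was not tested apart.

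Of 13 adipocyte markers 6 rose and 7 were not called (median 2.24, adjusted p = 0.59 by camera with an estimated correlation). All 13 had a mean linear signal of at least 70.3 in control lungs too, and 3 (Lpl, Pck1 and Slc2a4) are also in other lists. For Ucp1 that mean, 95.1, rests on 1 of the control mice (3, 25 and 258), so it does not show a clear signal in each. The median was at least 2.29 under quantile normalization and median centring, so it does not depend on the choice among these scalings. Median log2 signals of the arrays ran only from 8.6 to 8.75, so this test could hardly have come out otherwise and decides nothing further. More adipose tissue in the high fat samples stays open: within groups the 13 markers varied together between mice (mean correlation 0.66, above 100 percent of 1000 random lists). The correlation estimated by camera was higher for skeletal muscle (0.853), oxidative phosphorylation (0.835) and cardiac muscle (0.695) than for adipocyte markers (0.656), and lower for the other lists. Variation within groups does not show what differs between them. For fatty acid synthesis, the median was 0.4 with the adipocyte mean as a covariate and 0.46 without it, but the standard error of the diet term grew 2.35 times, so adipose tissue and diet cannot be told apart for these genes. A diet effect on adipocytes within or beside the lung stays open and untested.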

How the results depend on the processing

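The fit without 2 mice, replicate 1 of each group, was chosen after the data were seen. Counts of called genes (857) moved by over 1.5 times to 136 with eBayes without trend, to 515 (277 higher, 238 lower) with the mean of all probe sets, and to 307 without those 2 mice, which left fewer samples, as did the 1274 called probe sets (3486). Leaving out 1 mouse gave 721 to 3307 probe sets, 160 to 566 genes and 19 to 22 lists. Called lists (21) fell to 0 with an estimated correlation and 1 with fry. The club list turned to -0.01 without the 2 mice, for a cause not tested. Cox5b turned to -0.07 and Hbb-b2 to 0.08 with the mean of all probe sets, through probe sets that failed the filter, and Akt2 to -0.06 by a swap to a dimmer probe set not marked _x_at or _s_at. The b-Actin and Gapdh ratios of 3' to middle probe set differed by 0.052 and 0.001 on the log2 scale, against 0.225 and 0.251 for 3' to 5'.

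All other settings kept the 3 counts within 1.5 times (2504 to 3761 probe sets, 731 to 1157 genes, 17 to 24 lists). The median of all tested genes was 0.056 as deposited, 0.1 after quantile normalization and 0.146 after median centring. Replicate numbers did not pair the mice (correlations of deviations 0.167, 0.108 and -0.041), and with the replicate block 3052 probe sets, 737 genes and 24 lists were called. Of 161 genes named by the rule, 61 had other tested probe sets, 13 had one of opposite sign and 1, Hmgcs1, a called one. No probe set below a mean signal of 70.3 was tested in the main fit.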

Other observations

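The tests of other splits of the mice and the genes Nnt and the ribosomal protein family in this part were chosen after the data were seen.

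Several lists held only few called genes, some of them with large differences. Cxcl13, the B cell attracting chemokine, rose from 673 ± 77.6 to 2410 ± 820 (SD, n = 3 each; limma adjusted p = 0.00512; log2 1.8, and 1.19 in another probe set), while the chemokine receptor Ccr7 fell to 0.456 times the control level, and these were the called genes among 6 lymphoid follicle markers (camera adjusted p = 0.19). Apoc1, an apolipoprotein, rose 2.92-fold and was the called gene among 15 of cholesterol efflux (camera adjusted p = 0.849). The metallothionein Mt1 rose 2.41-fold and, with Pdk4, was called among 17 glucocorticoid response genes (median 0.34, camera adjusted p = 0.0743, but 0.022 with no filter and 0.0134 without replicate 1 of both groups). With 1 mouse left out the median of this list ran from 0.18 to 0.73, and its camera adjusted p reached 0.727 without high fat replicate 2. The glutathione peroxidase Gpx3 rose 1.61-fold as the called gene of 19 antioxidant genes (camera adjusted p = 0.19). Among 20 hypoxia targets Vegfa fell to 0.691 times, from 6180 ± 180 to 4270 ± 82.9 (SD, n = 3 each), with a log2 difference of -1.5 in another probe set, and Ndrg1 rose 1.4-fold (camera adjusted p = 0.839). Cd8b1 was the called gene of 5 thymus markers (camera adjusted p = 0.0743, and 0.0434 with median centring). Cxcl13 and Apoc1 stayed called with any 1 mouse left out, while Ccr7, Mt1, Gpx3, Vegfa and Ndrg1 did not (up to 0.148, Ndrg1 without control replicate 2).

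No member was called by limma among 24 proliferation, 16 immediate early, 10 MHC class II, 19 fibroblast, 11 platelet, 7 neural and 6 sex-linked genes, and the camera adjusted p of these lists was 0.834, 0.19, 0.468, 0.604, 0.468, 0.606 and 0.536. At an unadjusted p under 0.05 limma gave 2, 0, 3, 5, 1, 1 and 0 of these genes, and adjusted over the list alone the 3 MHC class II genes H2-Ab1, H2-Ob and Ctss were called (log2 0.65, -0.95 and -0.69). Nnt, the mitochondrial transhydrogenase, had 784 ± 26.5 in control and 1690 ± 61.8 in high fat mice (SD, n = 3 each; 2.15-fold, limma adjusted p = 0.00277), with a log2 difference of 1.02 in another tested probe set and a call in each fit with 1 mouse left out. A dim probe set that was not tested had 35.6 and 16.1 (log2 -1.4), and with the mean of all 3 Nnt was not called (0.24, limma adjusted p = 0.724). Some inbred substrains carry a deletion in Nnt, and the strain of the mice is not given in the sources used here. If the diet groups differed in substrain, every difference between them would be confounded with substrain. Of 43 cytosolic ribosomal protein genes, 12 rose and 0 fell, and their median was 0.106 as deposited but -0.06 after quantile normalization.

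For 3 against 3 mice there are 10 splits, too few for a share under 0.05. The real split, 1 of 10, gave 3486 probe sets, 857 genes and 21 lists, and the highest of the other splits gave 0, 2 and 18. The other splits hold the diet difference within their groups, so their low counts of probe sets and genes do not measure false calls.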
